A study of Danio rerio with 17 samples.

How the data were processed

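The measurements are read counts per gene in 17 pools of whole zebrafish embryos of the AB line, 10 embryos per pool, frozen at 72 hours post fertilization (hpf). Per the labels' protocols, RNA was extracted with TRIzol and a column kit, stranded libraries were made from poly(A) RNA, and all 17 libraries were sequenced together as 75 bp paired-end reads. Each deposited file holds whole-number read counts for 15316 named genes, with no normalization in the values, and 2 lines that name no gene (no feature and ambiguous). Per the submitters' processing notes, STAR, DESeq2 and the genome build danRer7 were used, with no versions or roles given. The counting tool, the gene annotation and the treatment of reads that match several genes are not given in the sources used here. Genes with near-identical copies (the hsp70, protocadherin, elastase, crystallin, he1, ggact, mep1a and vitellogenin families) are therefore uncertain as single genes.

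Libraries were grouped by their titles into 5 control, 6 glucose and 6 FFA pools. The treatment tag of 11 of the 17 libraries names another group than the title (all 6 glucose libraries and 5 of the FFA libraries). Glucose replicates 2 to 6 are tagged FFA, FFA replicates 2 to 6 glucose, and glucose replicate 1 control, so the tags nearly exchange the treatments, while the group sizes in the design text match the titles. Grouping by the tag was run as an alternative for the numbers of genes called alone. The labels do not say that the pools came from separate clutches or days, so p-values measure the spread between these pools. Whether control embryos were injected is not given in the sources used here.

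Counts assigned to genes ranged from 10.2 to 16.7 M per library. The no-feature line took 33.5 ± 2.70% of all counts in control (SD, n = 5), 32.1 ± 2.31% in glucose (n = 6) and 33.4 ± 1.88% in FFA (n = 6), and stayed out of library sizes and tests. Pairs of replicates differed by more than sampling noise in all 40 cases (chi-square per degree of freedom 4.26 to 67.4), so no library was counted as a duplicate.

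Counts were tested with edgeR 4.0.16 (R 4.3.3). Genes passing filterByExpr (minimum count 10) were kept, which left 13539, libraries were scaled by TMM, and the quasi-likelihood F-test was run in 1 fit with a mean per group and 14 residual degrees of freedom. The common biological coefficient of variation was 0.158. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. CPM were computed here from the deposited counts and the TMM-scaled library totals. The 41 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, and again with the correlation estimated from the data. Adjusted p-values of lists are over the 41 lists of a comparison. Members were also counted with p-values adjusted over the list alone.

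The lists were appetite orexigenic, appetite anorexigenic, appetite receptors, glycolysis, gluconeogenesis, lipogenesis, cholesterol synthesis, fatty acid oxidation, lipid transport and storage, insulin and IGF signalling, unfolded protein response, oxidative stress response, heat shock proteins, osmotic stress and inositol, ionocyte, glucocorticoid response, hypoxia response, circadian clock, cell cycle, p53 and apoptosis, photoreceptor, lens crystallin, neuron, glia and myelin, skeletal muscle, heart, erythrocyte, macrophage and neutrophil, inflammation, complement and interferon, liver secretory, exocrine pancreas, intestine, vitellogenin and yolk, hatching gland, keratinocyte and skin, cartilage and bone, extracellular matrix, pigment cell, ribosomal proteins, and mitochondrial respiration. Named genes followed a rule of the same date. It takes, per comparison, the 8 largest changes in each direction among called genes with a mean of at least 1 CPM, no overlap between the 2 groups and a gene name. It adds the 3 called members with the smallest p of each list that was called or had at least 3 called members, and a fixed panel of appetite genes, ins and pck1. Genes named outside the rule are said to be so.

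The procedure was tested on simulated counts in which 200 genes were changed. Each gene was drawn independently, without the variation shared by many genes that these libraries show. The shares of recovered genes and false calls therefore hold for independent genes alone. For glucose against control it recovered 70.6% of 1.5-fold, 84.4% of 2-fold and 98.5% of 4-fold changes among 13510 genes, with 1.17% false calls. For FFA against control these shares were 73.6%, 89.8% and 100% among 13507 genes, with 5.91% false calls. For FFA against glucose they were 78.1%, 90.6% and 97.2% among 13503 genes, with 2.73% false calls.

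The overlap of the glucose and FFA comparisons, which share 5 controls, was set beside 20 simulations of unchanged groups and splits of the controls into 2 and 3. Alternatives were RLE scaling, library size alone, no count filter, a mean of at least 5 CPM, robust dispersion, the replicate number as a block, fits of the 2 groups alone, limma-voom, DESeq2 1.42.0, grouping by the treatment tag, and leaving out each library in turn. Added after seeing the data were the no-feature share as a covariate and the removal of control replicates 1 and 2 and glucose replicate 4, which lay at 1 end of the within-group axis. Counting intervals are exact binomial 95% intervals and cover counting error only, and a floor of 3 counts stands for genes at 0. Gene order was taken from the RefSeq table of assembly GRCz12tu, which differs from the build of the files, so no coordinates are given. No genome sequence was used here.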

Results

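Gene expression was measured in whole zebrafish embryos at 72 hpf after excess glucose or excess fat. Glucose embryos were kept in 3% glucose from 24 hpf. FFA embryos received a BODIPY-labelled lipid in canola oil (1 mg/ml), injected into the yolk at 24 hpf. Each library came from a pool of 10 embryos, with 5 control, 6 glucose and 6 FFA libraries. Counts assigned to genes (M, mega-counts per library) were 13.6 ± 1.23 M in control (SD, n = 5), 13.6 ± 2.32 M in glucose (n = 6) and 13.4 ± 1.31 M in FFA (n = 6). Groups follow the sample titles, and the treatment tags of 11 libraries name another group. The tags nearly exchange the treatments: glucose replicates 2 to 6 are tagged FFA, FFA replicates 2 to 6 glucose, and glucose replicate 1 control. Were the tags right, most of what is given here for glucose would belong to FFA and the reverse. For 2 libraries the values go against the tags as given. On principal component 2 of all libraries (21.5% of variance), glucose replicate 1, tagged control, lay at 17.8. Controls lay from -26.9 to 7.02 and glucose replicates 2 to 6 from 10.5 to 32.4. FFA replicate 1, which shares its tag with glucose replicates 2 to 6, lay at -17.4. An exchange of the 2 treatment names alone is not decided by these values. In the order of the records the titles run control, glucose, FFA and the tags control, FFA, glucose. The sample numbers of the libraries also run control, FFA, glucose, so the tags follow the order of those numbers, not that of the titles. Grouped by the tags, 106 genes were called for glucose (titled FFA) against control, 1 for FFA (5 of 6 titled glucose) against control and 511 for FFA against glucose.

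Within groups, the libraries spread along 1 axis that held 55.0% of the within-group variance and followed the share of counts outside genes (Pearson r = 0.948, permutation p = 1e-05, the smallest the permutations can give, and Spearman rho = 0.922, permutation p = 2e-05, n = 17). Adjusted over the 2 relations computed, these were 2e-05 and 4e-05, and r was 0.913 without the 2 farthest libraries. Within control r was 0.997, within glucose 0.9497 and within FFA 0.877. The relation with depth was r = 0.513 (permutation p = 0.04) and rho = 0.554 (permutation p = 0.03), with r = 0.447 without the 2 farthest libraries. Photoreceptor and neuron genes lay highest at the end of the axis with the larger share outside genes, with medians 2.59 and 1.56 log2 units above the other end for 46 and 34 genes. All 73 ribosomal protein genes and all 12 heart genes ran the other way, with medians of -0.58 and -0.69. An alternative below removes 3 libraries at the end with the larger share, control replicates 1 and 2 and glucose replicate 4 (37.2, 28.6 and 42.5 on the axis). It keeps the farthest library, control replicate 4 at the other end (-43.3).

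Glucose against control asked how pools kept in excess sugar differ from control pools, with the parents of both not given. No pool is labelled as kept in another solute, so sugar and osmotic strength cannot be told apart. Genes of the digestive organs fell as shares of the counts of whole embryos. Organ size and developmental stage were not measured, so a change within the organs is not shown in either treatment. Of 24 measured exocrine pancreas genes 18 were lower and 0 higher (19 lower and 1 higher adjusted over the list alone), with a median log2 fold change of -0.998. The elastase gene ela2l fell from 317 ± 45.4 CPM in control (SD, n = 5) to 104 ± 15.2 CPM in glucose (n = 6), a log2 fold change of -1.60 ± 0.113 (SE, adjusted p = 1.09e-07). The phospholipase gene pla2g1b fell by 2.28 ± 0.156 on the log2 scale (adjusted p = 9.86e-08). Of 26 intestine genes 18 were lower (19 lower and 1 higher adjusted over the list alone), with a median of -0.67, among them the amino acid transporter slc6a19b (-1.68 ± 0.123, adjusted p = 1.48e-07), the chitinase chia.3 (-1.30 ± 0.107, adjusted p = 5.99e-07) and the bile acid binding protein gene fabp6 (-1.67 ± 0.175, adjusted p = 9.14e-06). Both lists passed camera with the preset correlation (adjusted p = 7.43e-54 and 6.41e-36) and with an estimated correlation (adjusted p = 0.00225 for each).

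In all, 1474 of 13539 genes were called in glucose, 795 higher and 679 lower, and 217 of them changed at least 2-fold (50 higher, 167 lower). At an unadjusted p under 0.05 there were 3396. Libraries of the 2 groups did not overlap for 934 genes (6.90%), where chance gives 0.433%. With library size alone in place of TMM the split was 652 higher and 856 lower, and with RLE scaling 715 and 738. Large rises included the light-induced cryptochrome cry5 (5.96 ± 0.358 CPM in control, 22.6 ± 1.91 in glucose, log2 1.92 ± 0.128, adjusted p = 6.97e-08), glucokinase gck, which phosphorylates glucose in the liver (1.92 ± 0.290, adjusted p = 0.000391), the HSP90 co-chaperone ahsa1a (1.5) and the clock gene per2 (1.3). Among called genes with a gene name, a mean of at least 1 CPM and no overlap, the largest falls were in the clustered protocadherin genes pcdh1g22, pcdh1g30 (-7.31) and pcdh1g26 (-3.83), the cytochrome P450 gene cyp2p9 (-6.56 ± 0.393, 33.9 ± 15.9 CPM in control and 0.349 ± 0.135 in glucose), the meprin mep1a.2 (-5.24), ggact.2 (-3.52), ggact.3 (-3.49) and ddx43 (-3.35). Genes outside these limits, such as pcdh1g29 and scg5, fell by more than several of them. The ggact.2 counts in the 6 glucose pools were 60, 0, 29, 32, 0 and 1. Without 1 library in turn ggact.2 ran from -4.18 to -3.22, pcdh1g30 from -7.94 to -7.00 and pcdh1g22 from -8.67 to -7.84. With 644 counts in control and 2 in glucose, pcdh1g22 was 376-fold lower (counting interval 104 to 3109). The no-feature share as a covariate, added after seeing the data, gave 2522 calls and the replicate number as a block 910, and 5 of 100 splits of these libraries, the real one included, called at least as many genes as the grouping without the covariate.

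Insulin and IGF signalling was the remaining list called in glucose with an estimated correlation (adjusted p = 0.0372, 0.00593 with the preset one). Its 31 measured genes had a median of -0.19, and 4 fell (8 adjusted over the list alone): the IGF binding protein genes igfbp2b (-0.50 ± 0.0933, adjusted p = 0.00244) and igfbp6b (-0.38), the glucose transporter slc2a1a (-0.89) and the transcription factor foxo3b (-0.23). The igfbp2b call stood in all 11 fits that left out a library. The igfbp6b call ended without control replicate 3, control replicate 4 or glucose replicate 1 (adjusted p 0.0506 to 0.0557), and that of slc2a1a without control replicates 1, 2 or 3 or glucose replicates 2, 3 or 5 (0.0593 to 0.114). The foxo3b call ended without any single library except control replicate 4 and glucose replicate 4 (0.0532 to 0.116). With control replicates 1 and 2 and glucose replicate 4 removed, the calls of igfbp6b (adjusted p = 0.0812), slc2a1a (0.281) and foxo3b (0.0574) also ended. That of slc2a1a ended with limma-voom (0.0644), and that of foxo3b in a fit of the 2 groups alone (0.0813) and with library size alone (0.0605). With the replicate number as a block all 3 ended (0.0810, 0.0968 and 0.0950).

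Lens crystallin genes were higher in glucose in 24 of 31 cases (30 adjusted over the list alone), with a median of 0.82 and cryaa at 1.28 ± 0.244 (adjusted p = 0.00272). The list's call ended with an estimated correlation (adjusted p = 0.406). Cell cycle genes included 11 that rose and 1 that fell of 42 (23 and 2 adjusted over the list alone), with the replication helicase subunits mcm3 (0.72) and mcm6 (0.36) higher and thymidine kinase tk1 lower (-1.14), and an adjusted p = 0.493 with an estimated correlation. Erythrocyte genes rose in 10 of 25 cases and fell in 1 (13 and 1 adjusted over the list alone), with the heme synthesis genes alas2 (0.74) and fech (0.96) higher (adjusted p = 0.440 with an estimated correlation). Liver secretory genes fell in 16 of 43 cases and rose in 4 (17 and 4 adjusted over the list alone), among them tdo2b (-2.37), a tryptophan-degrading enzyme, agxtb (-0.84) and cyp3a65 (-0.91), with an adjusted p = 0.622 with an estimated correlation. Ionocyte genes fell in 6 of 24 cases (9 adjusted over the list alone), including the ion transporter slc12a10.2 (-0.77) (adjusted p = 0.351 with an estimated correlation).

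Among metabolic lists in glucose, cholesterol synthesis had 3 genes higher and 2 lower of 27 (7 and 2 adjusted over the list alone), with idi1 at 0.42 and the LDL receptor ldlra at -0.48 (adjusted p = 0.833 with an estimated correlation). Glycolysis had 4 of 30 higher and 1 lower, gck and gpib (0.64) rising and aldoca falling (-0.89). Lipogenesis had 2 of 21 higher and 5 lower, including the phosphatidate phosphatase lpin1 (-0.82) and agpat2 (-0.34). Lipid transport and storage had 4 of 39 higher and 8 lower (6 and 12 adjusted over the list alone), with the fatty acid translocase cd36 (-0.62) and the liver protein gene fabp10a (-0.73) falling. Fatty acid oxidation had 2 of 35 higher and 1 lower, gluconeogenesis 0 of 17 higher and 1 lower, and mitochondrial respiration 2 of 49 higher and 1 lower. Of these metabolic lists only cholesterol synthesis was called, with the preset correlation alone. Preset adjusted p-values were 0.381 for glycolysis, 0.104 for lipogenesis and 0.106 for lipid transport and storage. They were 0.362 for fatty acid oxidation, 0.132 for gluconeogenesis and 0.241 for mitochondrial respiration. Of all genes 10.9% were called. The gluconeogenic enzyme gene pck1 fell by 0.62 ± 0.119 (337 ± 38.7 CPM in control, 220 ± 46.2 in glucose, adjusted p = 0.00307).

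Heat shock proteins had 6 of 23 higher and 2 lower in glucose, with the collagen chaperone serpinh1b at 0.73 and hspb9 at -0.92 (9 and 2 adjusted over the list alone, adjusted p = 0.493 with an estimated correlation). Skeletal muscle had 3 of 46 higher and 1 lower and extracellular matrix 2 of 23 higher (adjusted p = 0.926 for each with an estimated correlation). Their preset calls ended without control replicate 1, control replicate 2 or glucose replicate 5 for muscle (adjusted p 0.0628 to 0.266) and control replicate 1, control replicate 2 or glucose replicate 2 for matrix (0.0671 to 0.287). Both also ended with the 3 libraries removed (0.704 for muscle, 0.691 for matrix) and with the covariate (0.383 and 0.280). The matrix call ended as well in a fit of the 2 groups alone (0.0539) and at a mean of at least 5 CPM (0.0508). Circadian clock genes split into 4 higher and 10 lower of 34 (4 and 15 adjusted over the list alone). The list was not called. Counts higher and lower in the other lists, none called, were 3 and 3 of 26 for macrophage and neutrophil, 0 and 4 of 26 for inflammation, and 2 and 4 of 24 for complement and interferon. They were 3 and 2 of 30 for oxidative stress response, 1 and 0 of 31 for unfolded protein response, 1 and 2 of 26 for p53 and apoptosis, 2 and 3 of 22 for hypoxia response, 0 and 2 of 18 for glucocorticoid response and 2 and 1 of 9 for vitellogenin and yolk. They were 3 and 2 of 24 for cartilage and bone, 2 and 1 of 20 for pigment cell, 0 and 1 of 27 for keratinocyte and skin, 0 and 1 of 34 for neuron and 1 and 1 of 17 for glia and myelin. No member was called among 46 photoreceptor, 12 heart, 6 hatching gland, 16 osmotic stress and inositol and 73 ribosomal protein genes. Counts higher and lower adjusted over the list alone differed for unfolded protein response (0 and 0), macrophage and neutrophil (4 and 3), inflammation (0 and 5), complement and interferon (4 and 4), cartilage and bone (5 and 3), pigment cell (2 and 2) and mitochondrial respiration (2 and 0). Median, mean and test differed in sign for unfolded protein response, oxidative stress response, macrophage and neutrophil, complement and interferon, and cartilage and bone.

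**Figure D1:**
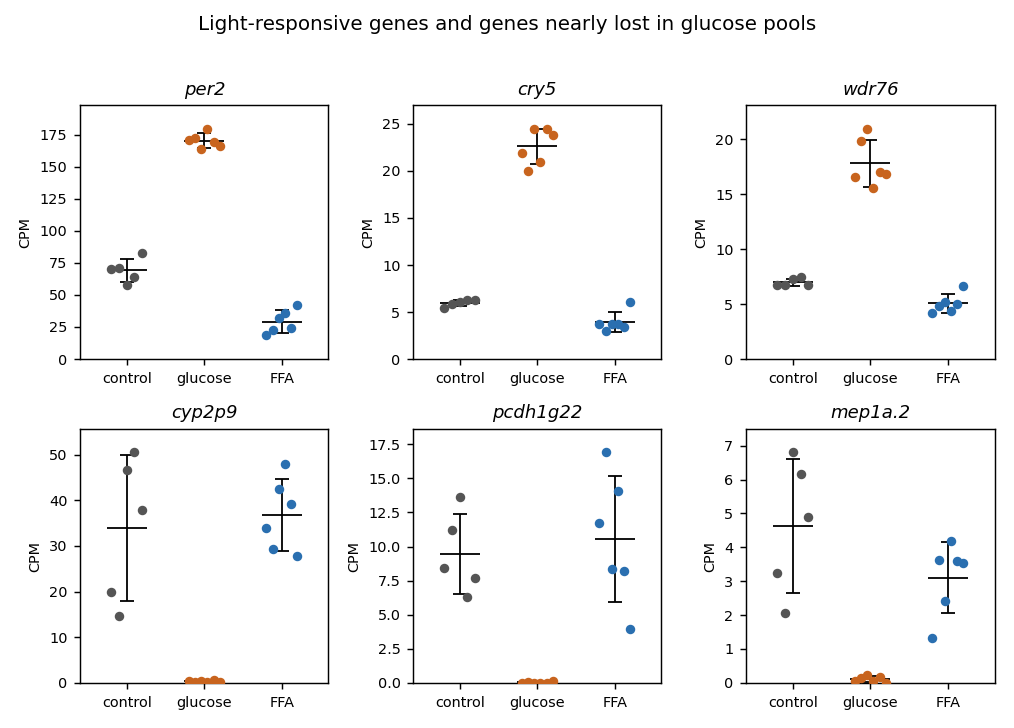
CPM (vertical axes, from 0) of 3 light-response genes (per2, cry5, wdr76) and 3 genes nearly lost in glucose (cyp2p9, pcdh1g22, mep1a.2) in each library; points are libraries and bars are the mean ± SD. The cyp2p9 means were 33.9 in control and 0.349 in glucose.

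**Figure D2:**
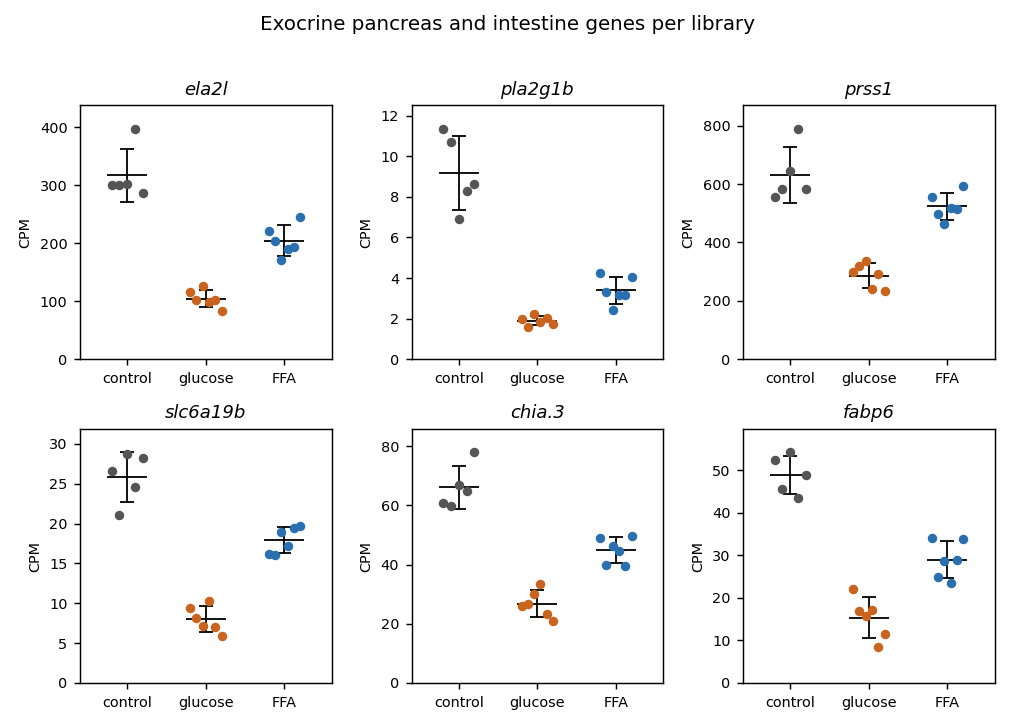
CPM (vertical axes, from 0) of 6 exocrine pancreas and intestine genes in each control, glucose and FFA library; points are libraries and bars are the mean ± SD. For ela2l the means were 317 in control, 104 in glucose and 204 in FFA.

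FFA against control asked how pools injected with the lipid differ from control pools. Whether controls were injected is not given, so lipid and injection cannot be told apart. Inflammation genes rose: 11 of 26 were higher and 0 lower (16 higher adjusted over the list alone), with a median log2 fold change of 0.80. The list was called with the preset (adjusted p = 1.95e-28) and an estimated correlation (adjusted p = 0.00696). The AP-1 gene fosl1a rose from 3.65 ± 0.754 CPM in control (SD, n = 5) to 51.04 ± 32.2 in FFA (n = 6), a log2 fold change of 3.80 ± 0.487 (adjusted p = 0.000321). The cytokine gene il1b rose by 2.51 ± 0.403 (adjusted p = 0.00262), the matrix metalloproteinase mmp9 by 1.81 ± 0.177 (adjusted p = 4.46e-05) and the stress transcription factor atf3 by 1.26 ± 0.139 (adjusted p = 0.000107). Macrophage and neutrophil markers had 4 of 26 higher and 1 lower (12 and 1 adjusted over the list alone) with a median of 0.33, including mmp13a (1.79) and mmp9, and an adjusted p = 0.0679 with an estimated correlation.

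Exocrine pancreas genes fell in FFA in 8 of 24 cases (14 adjusted over the list alone), with a median of -0.35 and an adjusted p = 0.0236 with an estimated correlation (1.73e-28 with the preset one). Examples were pla2g1b (-1.44 ± 0.148, adjusted p = 4.46e-05), the amylase amy2a (-0.74 ± 0.109, adjusted p = 0.00122) and ela2 (-0.63 ± 0.101, adjusted p = 0.00240). Intestine genes fell in 5 of 26 cases (7 adjusted over the list alone), with chia.3 at -0.56 and the alkaline phosphatase alpi.2 at -0.67 (adjusted p = 0.0868 with an estimated correlation). Hypoxia response genes rose in 3 of 22 cases (6 adjusted over the list alone), namely the glycolysis regulator pfkfb3 (0.77 ± 0.0712, adjusted p = 4.46e-05), igfbp1a (1.76 ± 0.274, adjusted p = 0.00198) and egln3 (0.55), and the list was called with an estimated correlation (adjusted p = 0.00696). The egln3 call ended without control replicate 1 or control replicate 3 (adjusted p 0.0538 and 0.0587), in a fit of the 2 groups alone (0.0668) and with the replicate number as a block (0.115).

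Over all genes, 246 were called in FFA, 149 higher and 97 lower, with 71 changed at least 2-fold (46 higher, 25 lower) and 1379 at an unadjusted p under 0.05. Libraries did not overlap for 311 genes (2.297%), where chance gives 0.433%. Among called genes with a gene name, a mean of at least 1 CPM and no overlap, heat shock genes of the hsp70 family showed the largest rises. These were hsp70l by 5.30 ± 0.724 (adjusted p = 0.000616), hsp70.3 by 4.84, hsp70.1 by 4.64 and hsp70.2 by 4.45. FFA libraries varied widely in them, with hsp70.3 at 89.9 ± 80.5 CPM (n = 6) against 3.102 ± 0.416 in control (n = 5). Of 23 heat shock proteins 7 were higher and 1 lower (8 and 3 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation). The hatching enzyme genes he1.1 (3.98 ± 0.447) and he1.2 (3.44 ± 0.510) rose, 2 of 6 hatching gland genes (adjusted p = 0.0673 with an estimated correlation). Without 1 library in turn he1.1 ran from 3.76 to 4.51, and the preset call of the list ended at a mean of at least 5 CPM (0.595). The detoxification genes cyp2k6 (-2.22), cyp2x8 (-1.99), sult5a1 (-1.61) and ugt5a3 (-1.36), the chemokine ccl19b (-1.35) and per2 (-1.25) showed large falls. The hsp70l call ended with limma-voom (adjusted p = 0.0814) and that of sult5a1 with the replicate number as a block (0.0583). Without control replicate 6 the count was 157, fitted without the glucose libraries 162, and with control replicates 1 and 2 and glucose replicate 4 removed 589. It was 649 with the no-feature share as a covariate, 382 with DESeq2 and 118 with the replicate number as a block. By the treatment tags, under which the FFA group is mostly libraries titled glucose, it was 1. That value concerns another set of libraries and does not bear on the FFA group by title. No control library is labelled as injected.

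Further lists in FFA had few called members. Glucocorticoid response had 4 of 18 higher and 1 lower, with cebpb (1.66), dusp1 (1.16) and sgk1 (0.83) rising (5 and 1 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation). In p53 and apoptosis 3 of 26 rose, btg2 (1.497), gadd45bb (0.86) and mdm2 (0.46), with an adjusted p = 0.322 with an estimated correlation. The mdm2 call ended without control replicates 1, 2 or 6 or any FFA replicate but 3 (adjusted p 0.0536 to 0.106), in a fit of the 2 groups alone (0.0578), with the block (0.176) and with the 3 libraries removed (0.110). Lipid transport and storage had 1 of 39 higher, the lipid droplet coat gene plin2 (1.00 ± 0.195, 9.01 ± 1.51 CPM in control and 18.1 ± 7.02 in FFA, adjusted p = 0.0102), and 3 lower. The plin2 call ended in a fit of the 2 groups alone (adjusted p = 0.0597). Oxidative stress response had 2 of 30 higher, including txnipa at 0.53 (adjusted p = 0.585 with an estimated correlation). Erythrocyte genes had 2 of 25 higher, slc4a1a (0.55) and hmbsb (0.35), with an adjusted p = 0.428 with an estimated correlation. The hmbsb call ended in a fit of the 2 groups alone (0.0513) and that of slc4a1a with the block (0.0585). Circadian clock genes had 2 of 34 lower, per2 and cry5 (-0.60), with an adjusted p = 0.523 with an estimated correlation. The preset call of the list (adjusted p = 0.000511) ended without control replicate 1 (0.212). With control replicates 1 and 2 and glucose replicate 4 removed the list turned direction and was not called (0.402). The cry5 call ended without control replicates 2, 3 or 6 or any FFA replicate but 6 (0.0523 to 0.0703) and in a fit of the 2 groups alone (0.108). The same 3 libraries removed ended the preset calls of oxidative stress response (0.732), p53 and apoptosis (0.305), complement and interferon (0.300), erythrocyte (0.279), pigment cell (0.148), cholesterol synthesis (0.0725) and heat shock proteins (0.0506).

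Lists called in FFA with the preset correlation alone, with their adjusted p with an estimated correlation, also included lens crystallin (0 of 31 called, median 0.40, adjusted p = 0.428), complement and interferon (1 of 24 higher, adjusted p = 0.428), pigment cell (0 of 20 called, adjusted p = 0.322), cartilage and bone (0 of 24 called, median -0.19, adjusted p = 0.0868). With the same 2 tests the others were cholesterol synthesis (1 of 27 higher, adjusted p = 0.691), fatty acid oxidation (0 of 35 called, adjusted p = 0.691), liver secretory (1 of 43 lower, adjusted p = 0.741) and mitochondrial respiration (0 of 49 called, adjusted p = 0.757). Not called by either test were glycolysis (2 of 30 lower), insulin and IGF signalling (2 of 31 higher), unfolded protein response (2 of 31 higher), osmotic stress and inositol (1 of 16 higher), ionocyte (1 of 24 lower), neuron (1 of 34 lower), vitellogenin and yolk (1 of 9 lower) and keratinocyte and skin (1 of 27 higher). Cell cycle, photoreceptor, glia and myelin, skeletal muscle, heart, extracellular matrix, ribosomal proteins, gluconeogenesis and lipogenesis had 0 called members. Counts higher and lower adjusted over the list alone differed for lipid transport and storage (2 and 4), oxidative stress response (6 and 0), erythrocyte (3 and 0), circadian clock (1 and 3), hatching gland (3 and 0), complement and interferon (4 and 0) and pigment cell (2 and 0). They also differed for liver secretory (1 and 7), glycolysis (0 and 3), insulin and IGF signalling (4 and 0), ionocyte (0 and 3), vitellogenin and yolk (1 and 2) and glia and myelin (1 and 0). Median, mean and test differed in sign for appetite receptors, lipogenesis, lipid transport and storage, insulin and IGF signalling, ionocyte, photoreceptor and extracellular matrix. Preset calls ended without control replicates 3 or 4 or FFA replicates 3 or 6 for cholesterol synthesis (adjusted p 0.122 to 0.473). That of liver secretory ended without control replicates 3 or 4 or FFA replicates 3 or 5 (0.0508 to 0.655). That of mitochondrial respiration ended without control replicates 3 or 4 or FFA replicates 4 or 5 (0.0583 to 0.518), and that of fatty acid oxidation without control replicates 3, 4 or 6 or FFA replicates 4 or 5 (0.0781 to 0.405). Calls ended too for cholesterol synthesis with limma-voom (0.0542) and the covariate (0.0704), liver secretory at a mean of at least 5 CPM (0.122) and fatty acid oxidation with the block (0.0607).

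**Figure D3:**
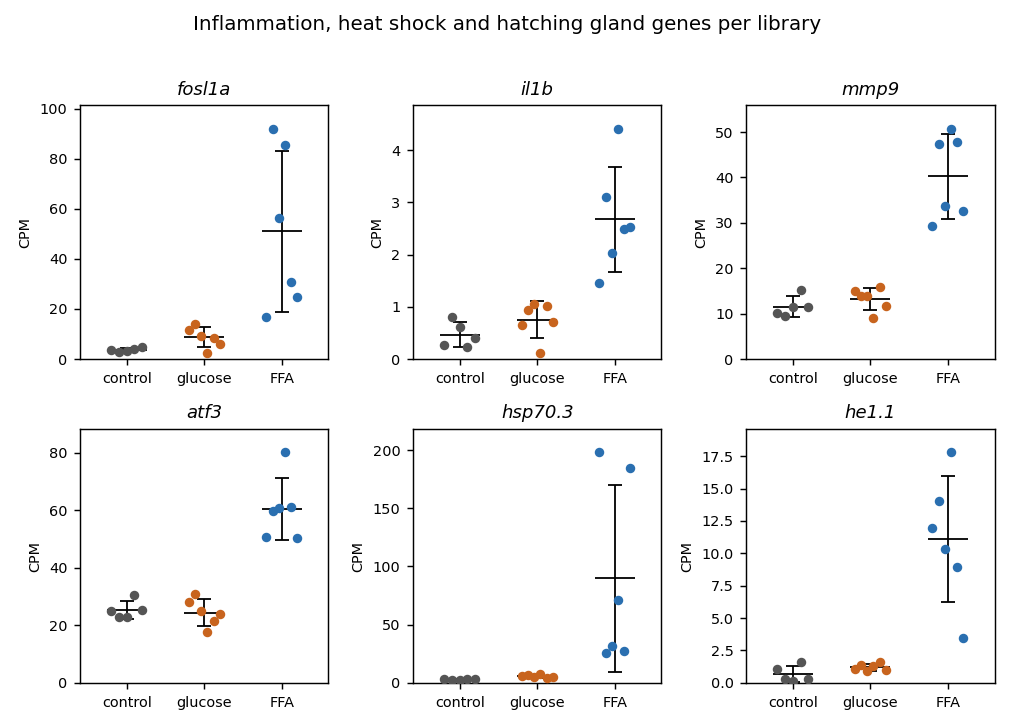
CPM (vertical axes, from 0) of 4 inflammation genes, the heat shock gene hsp70.3 and the hatching enzyme gene he1.1 in each library; points are libraries and bars are the mean ± SD. All 6 genes were higher in FFA, and hsp70.3 varied most between FFA libraries (SD 80.5 CPM).

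**Figure D4:**
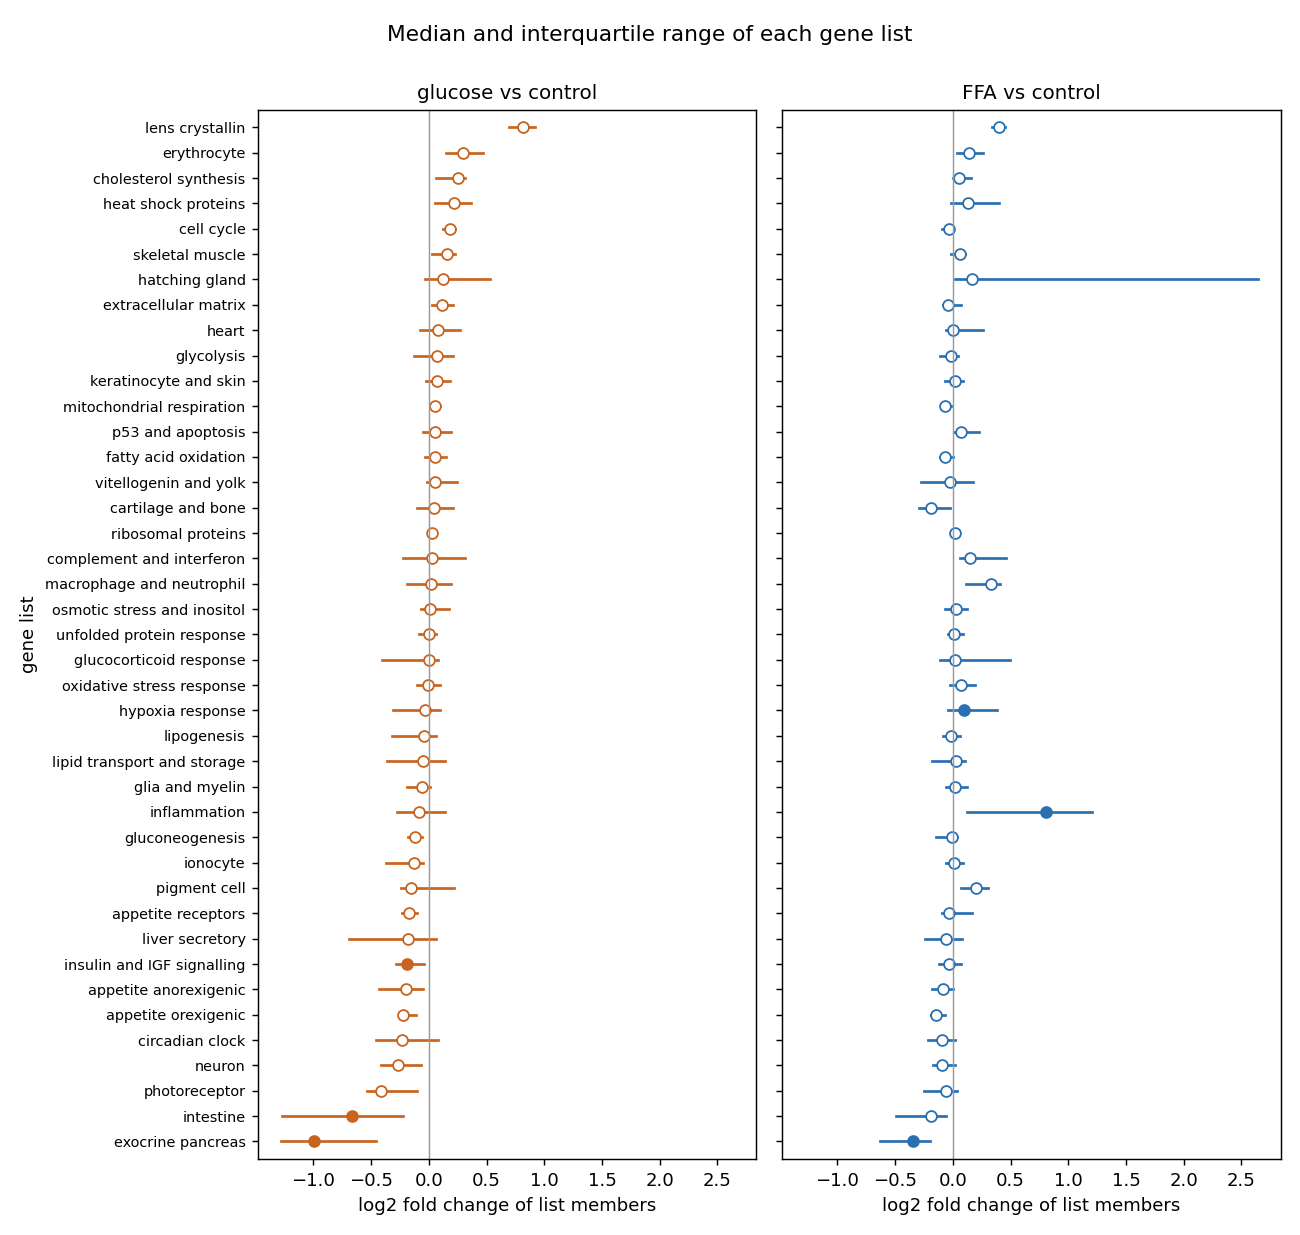
Median (circles) and interquartile range (lines) of the log2 fold changes of the members of each of the 41 lists, for glucose and FFA against control; filled circles mark an adjusted p under 0.05 with an estimated correlation. Exocrine pancreas is filled in both panels, at medians of -0.998 and -0.35.

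FFA against glucose asked how the treatments differ. FFA embryos were injected and glucose embryos were kept in glucose, so nutrient and route cannot be told apart. Inflammation genes were higher in FFA in 18 of 26 cases and lower in 0 (22 higher adjusted over the list alone), with a median of 1.05, junba at 2.18 ± 0.221 (adjusted p = 7.42e-06) and mmp9 at 1.61 ± 0.164 (adjusted p = 7.77e-06). Intestine genes were higher in 16 of 26 cases (17 adjusted over the list alone), with a median of 0.47 and slc6a19b at 1.15 ± 0.119 (adjusted p = 8.68e-06). Hypoxia response genes were higher in 6 and lower in 1 of 22 cases (9 and 2 adjusted over the list alone), with pfkfb3 at 0.77. Insulin and IGF signalling genes were higher in 6 and lower in 1 of 31 cases (6 and 1 adjusted over the list alone), with the binding protein genes igfbp1b at 2.38 ± 0.211 (adjusted p = 1.65e-06) and igfbp1a at 2.09 ± 0.261 (adjusted p = 5.81e-05). These 4 lists were called with an estimated correlation (adjusted p = 0.0421 for each).

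In this comparison 2299 genes were called, 1081 higher and 1218 lower in FFA, 218 of them at least 2-fold (177 higher, 41 lower), with 4165 at an unadjusted p under 0.05. With library size alone the split turned to 1339 higher and 1047 lower. Libraries did not overlap for 1177 genes (8.69%), where chance gives 0.216%. Protocadherin genes and cyp2p9, which fell in glucose, were among the higher genes with the largest differences (pcdh1g22 8.28, 8.01 to 8.84 without 1 library in turn, pcdh1g30 7.68, 7.42 to 8.31, and cyp2p9 6.68), and per2 (-2.55 ± 0.154), cry5 (-2.52 ± 0.125), cyp2x8 (-2.19), the yolk precursor vtg1 (-1.86), wdr76 (-1.82) and the DNA repair gene ddb2 (-1.59) were among the lower ones. Exocrine pancreas genes were higher in FFA in 15 of 24 cases and lower in 1, with prss1 at 0.87 and ela2l at 0.97 (17 and 1 adjusted over the list alone, adjusted p = 0.156 with an estimated correlation). Cell cycle genes were lower in 24 of 42 cases and higher in 1, with mcm3 at -0.70, mcm4 at -0.37 and tk1 at 1.23 (32 and 2 adjusted over the list alone, adjusted p = 0.305 with an estimated correlation). Pigment cell genes were higher in 10 and lower in 2 of 20, with pmela at 0.55 and gch2 at -0.81 (adjusted p = 0.528 with an estimated correlation). Macrophage and neutrophil markers were higher in 10 and lower in 1 of 26, with ncf1 at 0.58 (adjusted p = 0.275 with an estimated correlation). Liver secretory genes were higher in 13 and lower in 5 of 43, with tdo2b at 2.58 and ttr at 0.69 (adjusted p = 0.743 with an estimated correlation). Cartilage and bone genes were lower in 5 of 24, with col11a1a at -0.52 (adjusted p = 0.275 with an estimated correlation). With control replicates 1 and 2 and glucose replicate 4 removed 3738 genes were called, and with the no-feature share as a covariate 3978. By the treatment tags, which nearly exchange glucose and FFA, the count was 511.

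Other lists called for FFA against glucose with the preset correlation, none with an estimated one, were lens crystallin (5 of 31 lower, cryaa -1.06, adjusted p = 0.743 with an estimated correlation), glucocorticoid response (7 of 18 higher, adjusted p = 0.192 with an estimated correlation), ionocyte (6 of 24 higher, adjusted p = 0.305 with an estimated correlation) and extracellular matrix (1 of 23 higher and 7 lower, adjusted p = 0.743 with an estimated correlation). Mitochondrial respiration had 1 of 49 higher and 4 lower (adjusted p = 0.772 with an estimated correlation), and fatty acid oxidation 3 of 35 higher and 7 lower (adjusted p = 0.743 with an estimated correlation). Further lists were erythrocyte with 2 of 25 higher and 8 lower (0.743), complement and interferon with 9 of 24 higher and 1 lower (0.743), hatching gland with 3 of 6 higher and 1 lower (0.468) and glycolysis with 2 of 30 higher and 9 lower (0.354), each an adjusted p with an estimated correlation. Preset calls ended without glucose replicate 4 for liver secretory (adjusted p 0.104) and complement and interferon (0.154). The erythrocyte call ended without glucose replicate 2 or FFA replicate 3 (0.0513 and 0.0894), and that of fatty acid oxidation without glucose replicates 2 or 3 or FFA replicate 4 (0.0578 to 0.0670). Calls also ended without glucose replicate 3 or FFA replicates 3 or 4 for glycolysis (0.0617 to 0.0670), and glucose replicates 1 or 4 or FFA replicate 1 for hatching gland (0.0507 to 0.133). With the 3 libraries removed the calls of complement and interferon (0.194), hatching gland (0.0962) and liver secretory (0.0855) ended. With the covariate those of extracellular matrix (0.141), mitochondrial respiration (0.103), fatty acid oxidation (0.103) and erythrocyte (0.0688) did. At a mean of at least 5 CPM hatching gland (0.797), complement and interferon (0.0977, 0.0550 with no filter) and glycolysis (0.0625) were not called. With limma-voom hatching gland (0.108) and glycolysis (0.0838, 0.0544 with the block) were not. Called by neither were circadian clock (8 of 34 higher, 5 lower), heat shock proteins (5 of 23 higher, 5 lower), lipid transport and storage (10 of 39 higher, 3 lower), oxidative stress response (7 of 30 higher, 1 lower). Neither test called unfolded protein response (4 of 31 higher, 3 lower), p53 and apoptosis (4 of 26 higher, 1 lower), cholesterol synthesis (3 of 27 higher, 2 lower), lipogenesis (3 of 21 higher, 2 lower), vitellogenin and yolk (2 of 9 higher, 3 lower), keratinocyte and skin (1 of 27 higher, 4 lower) or the remaining lists, each with at most 3 called members. Counts higher and lower adjusted over the list alone differed for macrophage and neutrophil (12 and 1), liver secretory (18 and 8), pigment cell (11 and 2), cartilage and bone (1 and 9), ionocyte (7 and 0), extracellular matrix (2 and 7), mitochondrial respiration (1 and 3) and fatty acid oxidation (4 and 13). Such counts also differed for erythrocyte (2 and 9), complement and interferon (10 and 2), glycolysis (4 and 11), circadian clock (14 and 8), heat shock proteins (6 and 6), oxidative stress response (7 and 3), cholesterol synthesis (3 and 5) and, among the others, by at most 2 genes. Median, mean and test differed in sign for appetite orexigenic, heat shock proteins, osmotic stress and inositol, circadian clock, and heart.

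Against the shared controls, 88 genes were called in both treatments, 18 higher in both, 60 lower in both and 10 in opposite directions. Independent lists would share 8.75 higher and 4.86 lower genes if the controls were not shared. With the controls split into 2 and 3, a median of 0 genes was higher and 17.5 lower in both. Fewer genes were then called, with medians of 275.5 higher and 382.5 lower in glucose and 46.5 and 36 in FFA. The smaller shared counts therefore do not by themselves show how much the shared controls contribute. Genes lower in both included pla2g1b, ela2l, chia.3 and fabp6, and the lysozyme gene lyz was higher in both (0.65 and 0.53). The fabp6 call in FFA ended without control replicates 1, 3 or 6 or FFA replicates 2, 3, 4 or 5 (adjusted p 0.0537 to 0.0720), and that of lyz without control replicate 1 (0.0528), in a fit of the 2 groups alone (0.0643), with the 3 libraries removed (0.0691) and with the block (0.0884). With the block that of fabp6 ended as well (0.108). Of the 78 shared in direction, 27 differed between the treatments, such as ela2l (-1.60 and -0.64, adjusted p = 2.02e-05 for the difference). Genes opposite in direction included per2 (1.3 and -1.25), cry5 and junba (-1.11 and 1.07). The junba call in glucose ended with the 3 libraries removed (adjusted p = 0.0537). Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.278, against 0.547 in simulations without effects, and the covariance was 0.0238 against 0.0166 simulated, a difference of 0.00721. The same sign was seen in 58.2% of genes against 68.3% simulated. With the controls split, the median r was 0.053 (-0.316 to 0.243) and the median covariance 0.0054 (-0.0479 to 0.0235). The same sign was then seen in a median of 47.6% of genes. The simulations drew genes independently, so the covariance above the simulated one does not show a shared response. Without control replicate 3 or control replicate 6 the shared count was 46, and without FFA replicate 4 it was 49. It was 180 with the no-feature share as a covariate and 148 with control replicates 1 and 2 and glucose replicate 4 removed.

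Appetite genes were examined as a fixed panel, since the study asked about appetite regulation. The pools were whole embryos, and these data hold no measure of feeding. Both treatments were compared with the same 5 controls, so their results are not independent. The melanocortin precursor gene pomca, whose product restrains feeding, fell in both treatments, from 12.9 ± 1.64 CPM in control (SD, n = 5) to 8.42 ± 2.499 in glucose (n = 6, log2 -0.61 ± 0.164, adjusted p = 0.0248) and to 7.69 ± 0.756 in FFA (n = 6, log2 -0.74 ± 0.165, adjusted p = 0.0245). The treatments did not differ in it by the test (log2 -0.14 ± 0.161, adjusted p = 0.604). The pomca call in glucose ended without control replicate 1, control replicate 6, glucose replicate 2 or glucose replicate 5 (adjusted p 0.0504 to 0.0633), and in a fit of the 2 groups alone (0.0774). In FFA it ended without control replicates 1, 2 or 6 or FFA replicates 1 or 2 (0.0557 to 0.0719). With the replicate number as a block both ended (0.0536 in glucose, 0.0996 in FFA). The feeding-stimulating agrp (-0.26 ± 0.173 in glucose, -0.15 ± 0.172 in FFA) and npy (-0.24 ± 0.114 and -0.15 ± 0.113) were not called, nor were cart2 (-0.25 and -0.45), cart4 (-0.14 and -0.18) or insulin ins (-0.04 in each). The pck1 value in FFA was -0.26 ± 0.119 (adjusted p = 0.471). FFA exceeded glucose in pck1 by 0.36 ± 0.114 (adjusted p = 0.0390), a call that ended without glucose replicates 1, 3, 4 or 6 or FFA replicates 1, 2, 4 or 5 (0.0556 to 0.0886), and with the block (0.0558).

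Of 18 anorexigenic genes 3 fell in glucose, adcyap1a (-0.63 ± 0.121, adjusted p = 0.00280), pomca and the gut hormone gene pyyb (-0.72 ± 0.207, adjusted p = 0.0336), and 1 fell in FFA, pomca. These counts held adjusted over the list alone, and the list had an adjusted p = 0.493 in glucose and 0.428 in FFA with an estimated correlation. The pyyb call ended without control replicates 1, 2 or 6 or glucose replicates 1, 3, 5 or 6 (adjusted p 0.0508 to 0.0824), with the 3 libraries removed (0.170) and with the block (0.116). The preset calls of the list (0.0271 in glucose, 0.0482 in FFA) ended without control replicate 2 or control replicate 6 in glucose (0.0608 and 0.0637) and, in FFA, without control replicates 1, 2 or 6 or FFA replicates 1, 2, 3 or 6 (0.0768 to 0.134). They ended too with the 3 libraries removed (0.172 in glucose, 0.463 in FFA) and, in glucose, with the covariate (0.0808). In FFA RLE scaling (0.0595), library size alone (0.0605), no count filter (0.234), a mean of at least 5 CPM (0.1995) and the block (0.0602) each ended it. Of 7 orexigenic and 7 receptor genes, 0 passed the edgeR threshold in either treatment. Leptin genes were too low to test across all genes. The gene lepb had 35 counts in the 6 FFA libraries, all 6 above 0, and 1 count in the 5 control libraries, a 29.8-fold ratio with a counting interval of 5.004 to 1209 (two-sided exact permutation p = 0.0216, 0.0866 adjusted over 4 leptin tests). Glucose libraries held 1 lepb count. The gene lepa had 10 counts in FFA, 3 in control and 1 in glucose (two-sided exact permutation p = 0.323 for FFA and 0.106 for glucose).

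**Figure D5:**
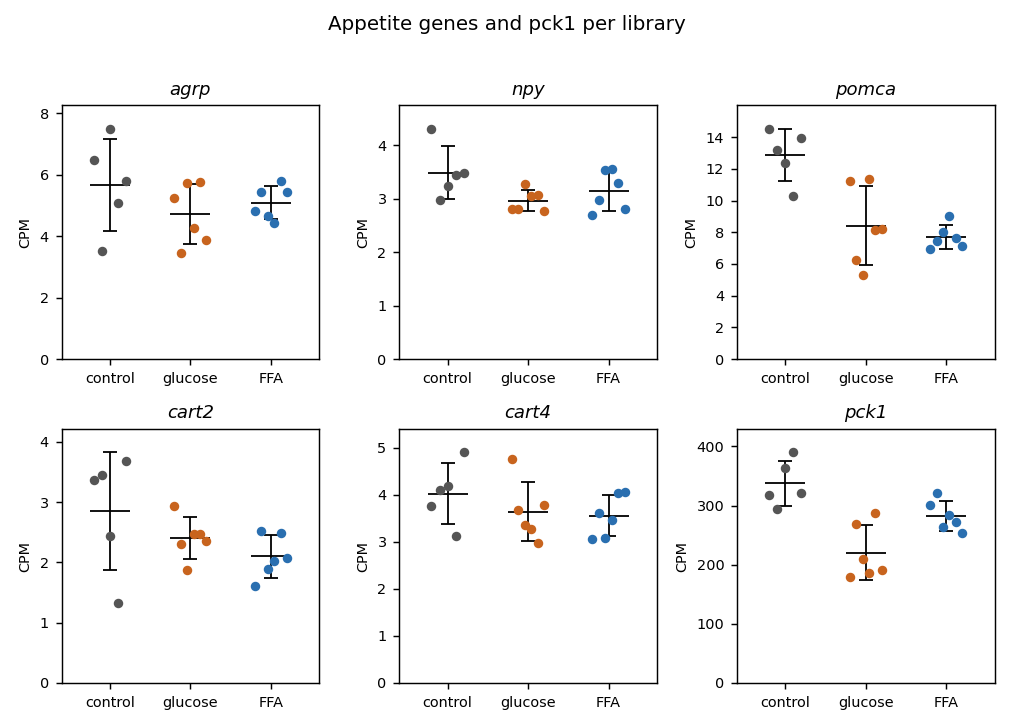
CPM (vertical axes, from 0) of 5 appetite genes and pck1 in each library; points are libraries and bars are the mean ± SD. The pomca means were 12.9 in control, 8.42 in glucose and 7.69 in FFA.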

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

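The light-response genes, the genes nearly lost in glucose, the inflammation genes, and the split test with the no-feature share as a covariate were chosen only after the results they concern were seen.

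The real grouping was set beside 100 of the 462 possible splits of the libraries of each comparison. For glucose against control, 5 of 100 splits, the real one included, called at least 1474 genes, and the highest other split called 4865, so chance was not excluded. The 4 other splits as large parted the libraries by at least 3.03 percentage points of no-feature share, against 1.43 in the real split, which points to a structure of the samples, and 92 splits called 0 genes. With that share as a covariate, a test thought of after this result, 1 of 100 splits called as many as the real 2522 genes and the highest other called 983. In FFA against control only the real split called as many genes (1 of 100 splits, 246 against 102 in the highest other). The same held in FFA against glucose (1 of 100, 2299 against 25). With 100 splits, 1 of 100 is the smallest share that can be found. For the 78 shared genes 1 of 100 regroupings gave as many (highest other 0), which says nothing of the shared controls, since lists that hold few or no called genes can share none. With the controls split, 0 higher and 17.5 lower genes were shared (median), with fewer genes called in each treatment. The numbers of lists called with the preset correlation were not beyond chance, with as many in 77 of 100 splits for glucose (13, highest other 27), 24 for FFA (21, highest other 25) and 19 for FFA against glucose (20, highest other 24).

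Single libraries stood far from the rest of their group in 29 of 534 tests, 5.43%, where chance gives about 1 in 20. The ratio given is the gap to the nearest library over the group's range, both in log2 CPM with a prior count of 2. In glucose replicate 4 ccl20a.3 (0.817), foxo3b (0.706), irg1l (0.739) and pax7a (0.721) were high and cd63 (0.660), evpla (0.707), il1b (0.730) and txnipa (0.706) were low. In control replicate 4 c3a.2 (0.853), dusp1 (0.755), ela2 (0.7995), ela2l (0.8501), pdk2b (0.839) and sgk1 (0.734) were high. In FFA replicate 6 cry5 (0.692) was high and he1.2 (0.826), hsf2 (0.682), pax7a (0.651) and tk1 (0.635) were low. FFA replicate 1 was low in btg2 (0.7002) and dusp1 (0.7697), FFA replicate 3 in adcyap1a (0.6335), FFA replicate 4 in actc1a (0.639), control replicate 1 in ctbs (0.743) and control replicate 3 in lim2.1 (0.735) and plin2 (0.788). Glucose replicate 1 was high in vtg1 (0.658), glucose replicate 2 in col1a1b (0.6445) and glucose replicate 6 in smyhc3 (0.6798).

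Light-response genes were higher in glucose in 10 of 10 cases and called lower in FFA in 4 of 10. The within-group axis of the libraries as the whole cause is argued against, since all 10 stayed called higher in glucose with the no-feature share as a covariate (log2 0.57 to 1.87) and without the 3 libraries at its end with the larger share (0.56 to 1.88), a fit that keeps the farthest library, control replicate 4 at the other end. Another time of day at freezing stays open for glucose, where 33.3% of the 30 other clock genes were called, all lower (exact 95% interval 17.3 to 52.8%, 10.8% of all other genes, Fisher exact p = 0.000838). For FFA it cannot be told apart from an effect of the treatment, since 0% of those 30 genes were called (interval to 11.6%, 1.79% of all other genes, Fisher exact p = 1). An effect of either treatment on these genes is a candidate explanation that was not tested apart from light or time of freezing, which the labels do not give.

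Of the genes called in glucose, 19 were at least 8-fold lower. Reads counted to a similarly named copy are argued against for the 4 genes of the cyp2p, mep1a and ggact stems, where 6 measured copies gained 3.15% of the lost CPM, with 0 called higher and 4 lower. For the 7 genes of the pcdh1g, scg and ddx stems this cannot be told apart from loss, since gains there were 31.7% (9 copies, 0 called), 0% (1 gene, too abundant to show a gain of this size) and 775.5%, together 210%, and the 20 ddx genes are no copies. Other parental haplotypes stay open, as the median coefficient of variation of these genes within control and FFA pools was at percentile 100 of matched random lists. Genes lost in blocks along the chromosome stay open too, since 35.3% of 17 placed genes had another within 3 neighbours. Random lists reached 11.8% at their 95th percentile, and samples of the same size from genes that fell 2-fold to 8-fold averaged 4.23% (percentile 99.8). The genes with such a neighbour all lay in 2 clusters of tandem copies (4 pcdh1g and 2 ggact genes). On 1 side of each cluster the neighbours pcdh1g31 (0.013) and kpnb3 (0.034) were not called. On the other side pcdh1g18 (-0.21) was not called, but ggact.1 was called lower (-1.765). Beside mep1a.2 and cyp2p9, mep1a.1 (-2.34) and cyp2p8 (-1.70) were called lower, and tnfrsf21 (-0.41) and cyp2p10 (0.55) were not called. A response to glucose may also account for them, and pools of known parents were not analysed here. The labels do not give the parents of any pool. If the glucose pools came from other parents, parents and glucose could not be told apart for any gene compared with glucose.

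Inflammation genes were higher in FFA in 11 of 26 cases. The list also holds AP-1 genes such as fosl1a, which are not particular to leukocytes. The medians that follow therefore concern the list as a whole and decide nothing for single genes. More leukocytes as the whole cause is argued against, since 25 leukocyte markers outside the list had a median log2 fold change of 0.33 (quartiles 0.11 and 0.39, 3 called higher), against a median of 0.80 for all 26 inflammation genes (quartiles 0.12 and 1.21). A single FFA pool is argued against, since the list stayed called without each of 6 pools in turn, also with an estimated correlation (adjusted p 0.00217 to 0.0182). Injection into the yolk cannot be told apart from the lipid, since 0 control libraries are labelled as injected. The lipid or the injection may have raised these genes, and neither was tested alone.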

How the results depend on the processing

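The covariate of the no-feature share and the removal of control replicates 1 and 2 and glucose replicate 4 were chosen after seeing the data. Of 259 named-gene results 207, and of 54 list results 10, kept direction and side of the threshold under every alternative that gave them a value. The tag grouping gave only numbers of genes called, DESeq2 and robust dispersion gave no list results, and genes below a mean of 5 CPM had no value under that filter. The replicate number as a block gave 910 genes for glucose, 118 for FFA and 28 shared genes, but the numbers do not pair the samples (4 of 16 pairs of libraries with the same number correlated above 0.1, range -0.76 to 0.518). Grouping by the treatment tag, which nearly exchanges glucose and FFA, gave 106, 1 and 511 genes for glucose, FFA and FFA against glucose. The covariate gave 2522, 649 and 3978, with 180 shared, and the removal gave 1189, 589 and 3738, with 148 shared. Fits of the 2 groups alone gave 162 for FFA and 47 shared, and DESeq2 gave 382 for FFA. Split controls, with fewer genes called, shared 17.5 lower genes (median). An estimated correlation left 3, 3 and 4 lists. Leaving out 1 library gave 1070 to 2019, 157 to 254 and 1654 to 2754 genes and 46 to 112 shared (157 without control replicate 6, 46 without control replicate 3 or 6, 49 without FFA replicate 4). Values near 0 changed sign without being called. Without 1 library ins ran from -0.12 to 0.051 (glucose), -0.10 to 0.044 (FFA) and -0.077 to 0.078 (FFA against glucose), and cart4 from -0.086 to 0.061 (FFA against glucose). For FFA against glucose ins was 0.028 with library size alone, 0.0049 at a mean of at least 5 CPM, 1.23e-05 with the block, 0.0082 with limma-voom and 0.105 with the covariate. The circadian clock list in FFA turned direction with the 3 libraries removed (adjusted p = 0.402). Apart from fewer libraries, the cause was not tested. At 3 counts the limit of detection was 0.173 to 0.307 CPM per library.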

Other observations

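The light-response genes and the genes nearly lost in glucose were chosen after their values were seen, apart from those the rule for named genes takes.

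Genes known to be induced by light in zebrafish embryos, with roles in the clock and in DNA repair, were picked by hand, and no test asked if light-induced genes as a class changed. In glucose the 10 genes had a median log2 fold change of 1.04, with cry5 at 1.92, wdr76 at 1.35, ddb2 at 1.27, cry-dash at 1.19 and xpc at 0.85, all called. In FFA their median was -0.30, all 10 lay below 0, and per2 (-1.25), cry5 (-0.60), wdr76 (-0.47) and cry1aa (-0.34) were called lower, the other 6 not called. The enzyme genes of serine synthesis psat1 (0.29 and 0.34) and phgdh (0.39 and 0.38) rose in both glucose and FFA and were named after their values were seen.

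The 19 genes nearly lost in glucose included clustered protocadherins, the meprin mep1a.2, cyp2p9, scg5 and the ammonium transporter gene rhcgl1. The gene scg5 was 87.5-fold lower (75 counts in control, 1 in glucose, counting interval 15.2 to 3502) and pcdh1gc5 52.5-fold lower (45 and 1 counts, 8.96 to 2120). The gene pcdh1g29 had 34 counts in control and 0 in glucose, at least 13.2-fold lower against 3 counts over the group. In FFA 4 of the 19 were called lower, cpo (-0.81), zgc:153968 (-1.24), rhcgl1 (-1.38) and zgc:153932 (-2.41).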
